A study of Homo sapiens with 2 samples.

How the data were processed

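RNA was measured in human foreskin fibroblasts, a skin fibroblast culture widely used to grow human cytomegalovirus (HCMV), at 5 min and 25 min of infection with the Towne strain at a multiplicity of infection of 10. There was 1 array per time point, 2 arrays in all. Each array was assigned to its time from the sample labels. No mock-infected or uninfected array was analysed here.

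Per the labels' protocols, cells were infected below full confluence, total RNA was purified on RNeasy columns and treated with DNase, and biotin-labelled cRNA was prepared by the standard Affymetrix procedure. The deposited values are intensity values per probe set on a linear scale, as judged from the values themselves: all lay above 0, and the means of both arrays were 180.4. The summary and normalization method that the authors used is not given in the sources used here, so any correction made before deposit is unknown. Both columns of values in the table were used, and 0 others were left aside.

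The table held 54675 probe sets, of which 62 were array controls. Among the others, the platform annotation listed 41091 to 1 gene, 1801 to several genes and 11721 to no gene. A probe set listed to several genes or to none was counted but given no gene name. Gene identifiers of 41037 single-gene probe sets matched a current RefSeq gene table, and 0 symbols differed from the listed ones. The table's genome build was not tied to the array, so no chromosome positions are given. Sex-linked marker genes were left out of gene-level values.

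Intensities were used as deposited, without rescaling, and taken to log2. A floor was set on each array at the 60th percentile of the 54613 probe sets that are not controls, which was 109.5 at 5 min and 111.8 at 25 min. Values below it were set to it. A probe set was compared where it lay above the floor on both arrays. Where it lay above the floor on 1 array only, the difference is a bound and is written as at least so many fold. A gene was represented by the brightest of its single-gene probe sets, and other probe sets of a gene are given where one that was measured on both arrays lay on the other side of 0, and for some other genes. Levels of different probe sets were compared only to choose the brightest or dimmest of a gene and to rank or group probe sets by brightness. Differences are log2 intensity at 25 min minus log2 intensity at 5 min, and a difference of 2-fold, 1 on the log2 scale, was counted. With 1 array per time point there is no test of infection time, no p-value and no interval over arrays: the number of arrays limits the precision of every value. The spread between probe sets of the same gene is given in place of a replicate error, and it covers measurement within these 2 arrays only. Bootstrap intervals in the closing section resample probe sets and likewise say nothing about other arrays.

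The lists of genes covered 23 groups: immediate-early and AP-1 genes, growth factor signalling feedback, NF-kB targets and cytokines, interferons and interferon-stimulated genes, HCMV receptors and entry factors, PML bodies and intrinsic defence, heat shock, the unfolded protein and integrated stress responses, p53 targets, proliferation, actin and SRF targets, fibroblast matrix, cholesterol synthesis, hypoxia and glycolysis, cytosolic ribosomal proteins, oxidative phosphorylation, splicing and RNA-binding factors, housekeeping, and markers of keratinocytes, endothelium, leukocytes, melanocytes and smooth muscle or pericytes. Each list's median was computed over members above the floor on at least 1 array. It was placed among the medians of 10000 random lists of the same size, drawn with replacement from genes in the same of 10 bins of brightness. The resulting percentile describes these 2 arrays and is not a test of infection time.

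Named genes followed a fixed rule. It took the 12 genes with the highest and the 12 with the lowest difference among genes above the floor on both arrays whose measured probe sets all moved in the same direction, without placeholder symbols. It took up to 5 genes per direction with the largest bound, 14 genes named in every case, and up to 4 members of each list with the largest absolute difference. The lists, this rule, the floor, the 2-fold threshold and the alternatives that follow were set before the data were examined. The alternatives were other scalings (centring on the median, quantile normalization, subtraction of a loess trend with a span of 0.3), floors at the 50th or 75th percentile or none, an offset of 32 before log2, removal of probe sets whose names end in x_at or s_at, thresholds of 1.5-fold and 3-fold, the mean or median of a gene's probe sets, list members above the floor on both arrays only, and 20 bins of brightness. Each alternative took its floor from the values it kept. Scaling to 9 of the 18 probe sets of spiked hybridisation controls and removal of values below the 1st percentile were added after the values had been seen.

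Counting and list steps were tested on simulated data made from the 5 min array, with 20431 probe sets above the floor that were left unchanged or shifted with the list below, and noise of SD 0.155 on the log2 scale. All 50 simulated differences of 1.5 and all 50 of -1.5 were found beyond 2-fold, with 0 of the 20431, while 0 of 50 differences of 0.5 were found. These differences were planted only in genes well above the floor. The noise was normally distributed, with an SD below the 0.18 seen across real probe sets. The 0 calls among unchanged probe sets thus give no rate of false calls for the real arrays. A simulated list of 30 genes shifted by 0.3 reached a percentile of 100, and an unshifted one stood at 31.2. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.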

Results

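Host transcripts were profiled on Affymetrix arrays in human foreskin fibroblasts at 5 min and 25 min of infection with the Towne strain of human cytomegalovirus, a herpesvirus that establishes lifelong infection. The comparison asks how host gene expression differs between these early points of virus entry. Each time point had 1 array, so every difference below has no replicate check. The median intensity of the 54613 probe sets that are not controls was 91.8 at 5 min and 93.9 at 25 min, and the highest was 9027 and 9801.

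The fibroblasts at 25 min had nearly the same transcript profile as those at 5 min. Of 20519 probe sets above the floor on both arrays, 99.9% lay within 2-fold and 99.2% within 1.5-fold. Those transcripts of the classic first responders to receptor signalling that could be measured were at like levels: EGR1, a zinc finger transcription factor, read 1593 at 5 min and 1668 at 25 min, and JUN, a subunit of AP-1, read 597 and 561. Some others, FOS among them, were below the floor on both arrays. The clearest difference carried by many probe sets of the same gene was in MALAT1, a long noncoding RNA retained in nuclear speckles, which was lower at 25 min in 12 of 12 probe sets. MALAT1 itself stayed within 2-fold. In all, 8 genes above the floor on both arrays differed by 2-fold, each on the strength of a single probe set. Bounds of at least 2-fold were found for 31 genes higher and 5 lower.

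Across probe sets, log2 values of the arrays correlated with a Pearson r of 0.983, and 0.985 among those above the floor on both (probe sets are not independent replicates). The median difference was -0.02 on the log2 scale with an SD of 0.18 across probe sets, and 95% of differences fell between -0.33 and 0.37. In total 23 probe sets were higher and 6 lower by 2-fold at 25 min. Scaling to the spiked controls lowered every difference by 0.11, so that positive differences under that size became negative and the median of all probe sets became -0.12, and turned that split into 15 higher and 8 lower. For 4173 genes with at least 2 measured probe sets, the differences of the 2 brightest disagreed by a median of 0.15 and by 0.49 at the 95th percentile, and they correlated with a Pearson r of only 0.081 across genes.

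At gene level, 7 of 11117 genes above the floor on both arrays were higher by 2-fold at 25 min and 1 was lower. SAAL1 read 122 at 5 min and 556 at 25 min, 4.56-fold higher. LMAN1L, related to a mannose-binding lectin of the secretory pathway, was 4.01-fold higher. SNTB2, a syntrophin that binds the dystrophin complex, was 3.15-fold higher. SMUG1, a uracil-DNA glycosylase of base excision repair, was 2.90-fold higher, and DLG3, a membrane-associated scaffold protein, 2.78-fold. STX4, a syntaxin of the plasma membrane that takes part in vesicle fusion, was 2.72-fold higher, and NMRK1, a nicotinamide riboside kinase, 2.18-fold. The gene lower by 2-fold was RUNX1T1, a transcriptional corepressor, which read 829 at 5 min and 125 at 25 min, 6.61-fold lower.

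The same genes' other probe sets gave small differences. The other 3 measured probe sets of RUNX1T1 had a median log2 difference of -0.20, ranging from -0.40 to 0.30, against -2.72 for the brightest. Those of SNTB2 had a median of -0.21, opposite to the 1.66 of its brightest. The second probe set gave 0.12 for DLG3 and 0.13 for STX4. Of the 8 genes beyond 2-fold, 4 had a second measured probe set, and in 0 of them was the second brightest beyond 1.5-fold in the same direction. RUNX1T1 and SNTB2 fall outside the naming rule because their probe sets disagreed, and were named after their values were seen. With a gene's probe sets averaged, 0 genes were lower by 2-fold and 8 were higher. Bounds from probe sets above the floor on 1 array only entered these averages, so the 8 are not simply the genes named above. STX4, for example, fell to 0.79. With the floor at the 75th percentile, 0 were lower and 2 higher. Probe sets whose names end in x_at or s_at can read more than their listed gene. Without them, and with the floor set anew from the rest, the difference was -0.05 for NMRK1 and 0.13 for STX4. SMUG1 then had no probe set above the floor. The floor in that setting was lower, 96.5 at 5 min and 98.6 at 25 min. With it 10 genes were higher and 1 lower by 2-fold, against 7 and 1.

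**Figure D1:**
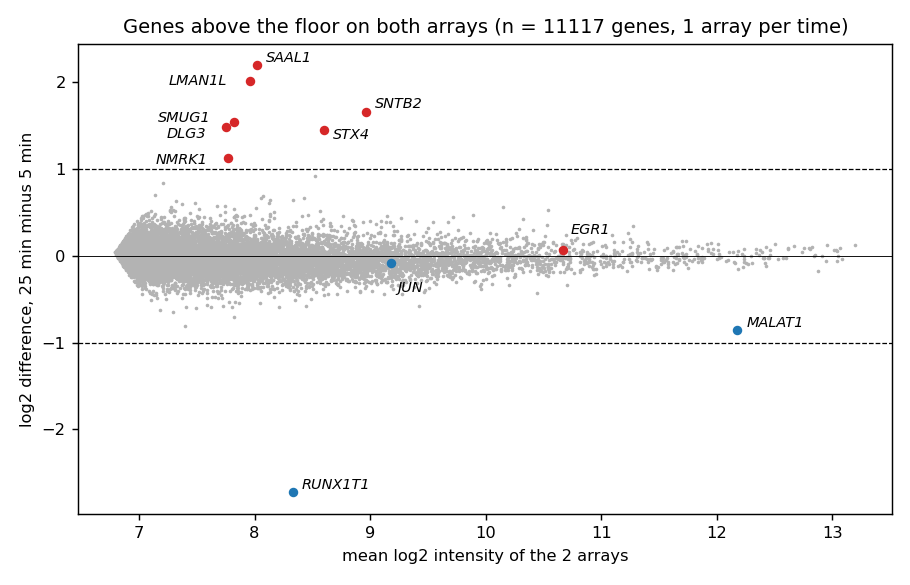
Log2 difference (25 min minus 5 min) of each of 11117 genes against its mean log2 intensity on the 2 arrays, with 1 array per time point; dashed lines mark 2-fold. The 7 genes higher and 1 lower by 2-fold are labelled with MALAT1, EGR1 and JUN, red above 0 and blue below, and MALAT1 stands at -0.86 among bright genes whose differences lie near 0.

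MALAT1 was lower at 25 min in every probe set measured. Its brightest read 6236 at 5 min and 3439 at 25 min, 1.81-fold lower. Over its 12 probe sets the median log2 difference was -0.71 (SD 0.31 across probe sets), from -0.89 to -0.03, and 7 of the 12 were lower by at least 1.5-fold. Probe sets of the same transcript are not independent samples of it, and 11 of the 12 have names ending in x_at or s_at. GAPDH, a glycolytic enzyme used as a reference, read 7327 and 7312 in its brightest probe set, with differences from -0.01 to 0.02 over 3. ACTB, cytoplasmic actin, read 7009 and 7535, a difference of 0.10 that is removed by scaling to the spiked controls. Of the 6 probe sets lower by 2-fold, 3 were listed to 2 genes each and so have no gene name here: they were 3.11-fold, 2.72-fold and 2.58-fold lower, the first at 895 and 288.

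**Figure D2:**
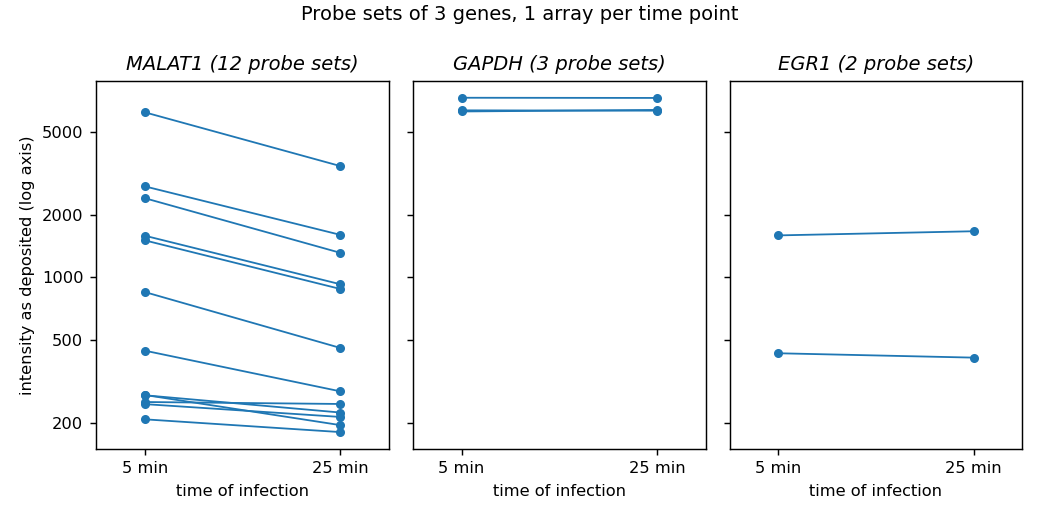
Deposited intensity on a log axis at 5 min and 25 min for each probe set above the floor on both arrays of MALAT1 (12), GAPDH (3) and EGR1 (2), with a line joining the values of a probe set and 1 array per time point. All 12 lines of MALAT1 slope down, from 6236 to 3439 in the brightest, and those of GAPDH are nearly level.

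The other genes with the lowest differences lay within 2-fold. FER, a cytoplasmic tyrosine kinase, had a log2 difference of -0.81 in its brightest probe set and -0.11 in its other measured one. MTAP, which salvages methylthioadenosine, stood at -0.65 and -0.35 in its 2 measured probe sets. RICTOR, a component of an mTOR complex, stood at -0.59 and lay between -0.59 and -0.31 in 3 probe sets. FNIP1, a partner of folliculin, stood at -0.58 and -0.33. DICER1, the ribonuclease that makes mature microRNAs, stood at -0.55 and -0.01 in its 2 measured probe sets. ND6, a mitochondrially encoded subunit of complex I, was at -0.57, and HS3ST5, a heparan sulfate sulfotransferase, at -0.55. MAGEC2 stood at -0.63, MUC12 at -0.61, SPATA16 at -0.60 and SNHG24 at -0.57, each on 1 measured probe set.

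Among genes with the highest differences short of 2-fold, FGF5, a secreted fibroblast growth factor, was at 0.92 and lay between 0.12 and 0.92 in 3 probe sets, with a median of 0.71. GTF2I, a general transcription factor, was at 0.83 on 1 probe set. STIP1, a co-chaperone that links heat shock proteins, was at 0.69 in its brightest probe set and 0.00134 in its other. SLC71A3P was at 0.69, CNTFR-AS1 at 0.66 and DHX37, an RNA helicase of ribosome assembly, at 0.64, each on 1 measured probe set.

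Further genes were bright enough to be measured on 1 array alone. A total of 31 genes were above the floor at 25 min only and at least 2-fold higher, and 5 were above it at 5 min only and at least 2-fold lower. ARNT, a partner of hypoxia-inducible factors, read 104 at 5 min and 1405 at 25 min, at least 12.8-fold higher, but its other measured probe set had a difference of 0.17, and without probe sets whose names end in x_at or s_at its difference was 0.02, on a probe set close to the floor. ESPL1, the protease that opens sister chromatids, was at least 9.94-fold higher, with -0.22 in its other measured probe set. FER1L5 was at least 9.01-fold, ABCG5, a sterol transporter, at least 6.17-fold and PKD1, which encodes polycystin, at least 5.90-fold higher, the last with 0.11 in its other measured probe set. In the opposite direction, CLN8-AS1 was at least 4.95-fold lower, MNAT1, an assembly factor of the CDK-activating kinase, at least 4.31-fold, and MAP2K4, a kinase of the JNK pathway, at least 4.01-fold. LIMD2 was at least 2.45-fold lower and TAPT1-AS1 at least 2.38-fold. Of the probe sets with such bounds, 23 of 62 in the higher direction and 5 of 10 in the lower had a value below the 5th percentile of the array on which they were dim.

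The genes of fixed lists stayed close together on the arrays. The 23 lists held 591 different genes with a single-gene probe set, 505 of them above the floor on both arrays. In their brightest probe sets, 0 of these 505 differed by 2-fold. Other probe sets of some members differed more, such as 1 of FN1 at 1.80 and those of THBS1 from -0.93 to 1.31. By brightest probe set, MALAT1 was the 1 member lower by 1.5-fold, and 0 were higher by 1.5-fold. Another 22 were above the floor on 1 array only, and 3 of these, named after their values were seen, were at least 2-fold higher: TIGAR (4.77-fold), NSDHL (4.62-fold, with 0.03 in its other measured probe set) and EGLN3 (2.89-fold). By chance about 1.15 of the 23 lists would have a median outside the central 95% of random lists, and 3 did. Alongside these lists, the 5′ probe sets of control transcripts were higher at 25 min, by 0.30 for GAPDH and 0.42 for ACTB.

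Signalling-induced genes were near level. Of 39 measured immediate-early and AP-1 genes, all within 2-fold, 15 were higher and 24 lower, with a median of -0.03 at the 60.7th percentile, which was positive after quantile or loess normalization. Another 6 genes of this list were below the floor on both arrays, among them FOS, the partner of JUN in AP-1, at 90.7 and 93.4. EGR1 had log2 differences of 0.07 and -0.07 in its 2 measured probe sets, IER2 of -0.11, JUNB of -0.28 and ATF3, a stress-induced factor, of 0.22. PHLDA1 was at 0.23 in its brightest of 6, which ranged from -0.30 to 0.47, and MCL1, an inhibitor of apoptosis, was at -0.34 in its brightest probe set with others up to 1.22. Growth factor feedback genes, 4 higher and 11 lower of 15, had a median of -0.05 at the 28.3rd percentile. VEGFA, an angiogenic growth factor, was at -0.44 in its brightest probe set with others up to 0.36, EREG at -0.31 and ETV5 at -0.26 with others up to 0.03.

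The measured innate immune genes likewise lay within 2-fold. Of 25 measured NF-kB targets and cytokines, 12 were higher and 13 lower, with a median of 0.02 at the 93.9th percentile and a mean of -0.01, and the median was negative after scaling to the spiked controls. NFKBIA, the inhibitor that NF-kB itself induces, was at -0.21, and CXCL8, a neutrophil chemokine, at 0.04 and 0.42 in its 2 measured probe sets. SOD2, mitochondrial superoxide dismutase, was at -0.49, NFKBIZ at -0.39 and NFKBIB at 0.36. IL6 read 107 at 5 min and 113 at 25 min, next to the floor. Another 11 genes of this list, TNF and PTGS2 among them, were below the floor on both arrays. Of 24 measured interferon and interferon-stimulated genes, 15 were higher and 9 lower, with a median of 0.02 at the 87.6th percentile that was also negative after scaling to the spiked controls. ISG15, a ubiquitin-like modifier, was at 0.02, SAMD9 at -0.36, GBP2 at -0.28 and OAS3 at 0.25. Another 16 genes of this list were below the floor on both arrays, among them IFIT1, an RNA-binding antiviral protein.

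Genes for the virus's receptors and for its nuclear restriction also lay within 2-fold. Of 29 measured HCMV receptor and entry factor genes, 9 were higher and 20 lower, with a median of -0.07 at the 6.84th percentile. EGFR, the epidermal growth factor receptor, was at -0.17 in its brightest probe set and between -0.30 and 0.81 over 8. PDGFRA, a receptor for HCMV in fibroblasts, was at -0.17, SDC4, a heparan sulfate proteoglycan, at -0.35, and BSG, basigin, at 0.27. Of 17 measured genes of PML bodies and intrinsic defence, which restrict incoming viral genomes, 3 were higher and 14 lower. Their median of -0.14 was at the 1.11th percentile of random lists, and at the 17.7th without probe sets whose names end in x_at or s_at. DAXX was at -0.33, ATRX at -0.28, APOBEC3C at -0.24 and PML itself at 0.25 in its brightest probe set with others down to -0.16.

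Of 29 measured splicing and RNA-binding factor genes, 4 were higher and 25 lower, with a median of -0.10 at the 2.15th percentile, and at the 3.99th after subtraction of a loess trend. Apart from MALAT1, SRSF6, a splicing factor, was at -0.41, SF3B1, a part of the spliceosome, at -0.30 with others up to 0.23, and RBM39 at -0.23. Heat shock genes, 5 higher and 10 lower of 15, had a median of -0.09 at the 9.56th percentile, with DNAJB4 at 0.34 and DNAJB6 at -0.19, and HSP90AB1 was at -0.15 in its brightest probe set with others up to 0.31. The median of this list lay between -0.20 and 0.00459 over the alternatives. Unfolded protein and integrated stress response genes, 8 higher and 16 lower of 24, had a median of -0.05 at the 37.3rd percentile, with ASNS, asparagine synthetase, at -0.28 and SESN2 at -0.25 and 0.16 in its 2 measured probe sets. For p53 targets, 6 higher and 10 lower of 16, the median was -0.04 at the 54.4th percentile, positive after loess. The mean was 0.11 with bounds such as that of TIGAR and -0.03 over the 16. CDKN1A, the p21 cell cycle inhibitor, was at -0.21 and BAX at 0.23.

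Growth and structural genes gave medians close to 0. Proliferation genes, 14 higher and 22 lower of 36, had a median of -0.05 at the 50.2nd percentile, which was positive after loess, with CENPF at -0.30, TOP2A at -0.21 with others up to 0.06, and CCNA2, a cyclin, at 0.25 and -0.08 in its 2 measured probe sets. Actin and SRF target genes, 11 higher and 10 lower of 21, had a median of 0.01 at the 90.9th percentile, negative after scaling to the spiked controls, with ACTG2 at 0.48 and TPM4 at 0.26. Fibroblast matrix genes, 14 higher and 21 lower of 35, had a median of -0.04 at the 52.8th percentile. Over the alternatives the median lay between -0.14 and 0.02 and the percentile between 18.3 and 96.6. FN1, fibronectin, was at -0.15 in its brightest probe set with others up to 1.80, and MMP14, a membrane-bound protease, was at 0.19.

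Metabolic lists were close to 0 as well. Cholesterol synthesis genes, 5 higher and 11 lower of 16, had a median of -0.08 at the 13.9th percentile. Their mean was 0.05 with bounds such as that of NSDHL and -0.08 over the 16. LSS, lanosterol synthase, was at -0.29 and 0.22 in its 2 measured probe sets, and SQLE at -0.17 in its brightest and between -0.37 and 0.26 over 3. Hypoxia and glycolysis genes, 7 higher and 14 lower of 21, had a median of -0.06 at the 20.5th percentile. Their mean was 0.02 with bounds such as that of EGLN3 and -0.06 over the 21, with ENO2 at -0.27 and PFKFB4 at 0.37 and -0.09 in its 2 measured probe sets. Cytosolic ribosomal protein genes, 15 higher and 35 lower of 50, had a median of -0.03 at the 69.9th percentile, with RPL34 at -0.13 and RPL6 at 0.11. Oxidative phosphorylation genes, 17 higher and 29 lower of 46, had a median of -0.03 at the 79.4th percentile, positive after loess, with NDUFS1 at -0.24. Housekeeping genes, 12 higher and 11 lower of 23, had a median of 0.01 at the 95.4th percentile, negative after scaling to the spiked controls, with RAB7A at 0.42 and -0.03 in its 2 measured probe sets and SDHA at -0.28.

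Markers of other cell types differed by less than 2-fold as well. Leukocyte markers were higher in 7 of 7 measured genes, 4 of 7 after scaling to the spiked controls, with a median of 0.13 at the 98.5th percentile, and at the 78.2nd without probe sets whose names end in x_at or s_at. AIF1 read 168 and 196 in its brightest probe set, with 0.01 and 0.03 in the other 2 measured, CSF1R 186 and 211, and LAPTM5 137 and 154. Keratinocyte markers, 1 higher and 3 lower of 4, had a median of -0.06 at the 28.3rd percentile and a mean of 0.00252 (-0.05 over the 4), with SFN at -0.13. The keratinocyte median lay between -0.16 and 0.05 over the alternatives, and its percentile between 20.8 and 83.9. Endothelial markers, 2 higher and 3 lower of 5, had a median of -0.04 at the 23.5th percentile, with PECAM1 at -0.28 and 0.12 in its 2 measured probe sets and VWF at 0.24 and 0.01. The endothelial median lay between -0.28 and 0.11 over the alternatives, and its percentile between 6.64 and 97.1. Melanocyte markers, 4 higher and 3 lower of 7, had a median of 0.03 at the 70.4th percentile and a mean of -0.08, and the median was negative after scaling to the spiked controls. MITF was at -0.32 and TYRP1 at -0.30. Smooth muscle and pericyte markers, 5 higher and 4 lower of 9 but 3 and 6 after scaling to the spiked controls, had a median of -0.00485 at the 51.2nd percentile and a mean of 0.08, with RGS5 at 0.44 and -0.03 in its 2 measured probe sets. That median lay between -0.11 and 0.02 over the alternatives.

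**Figure D3:**
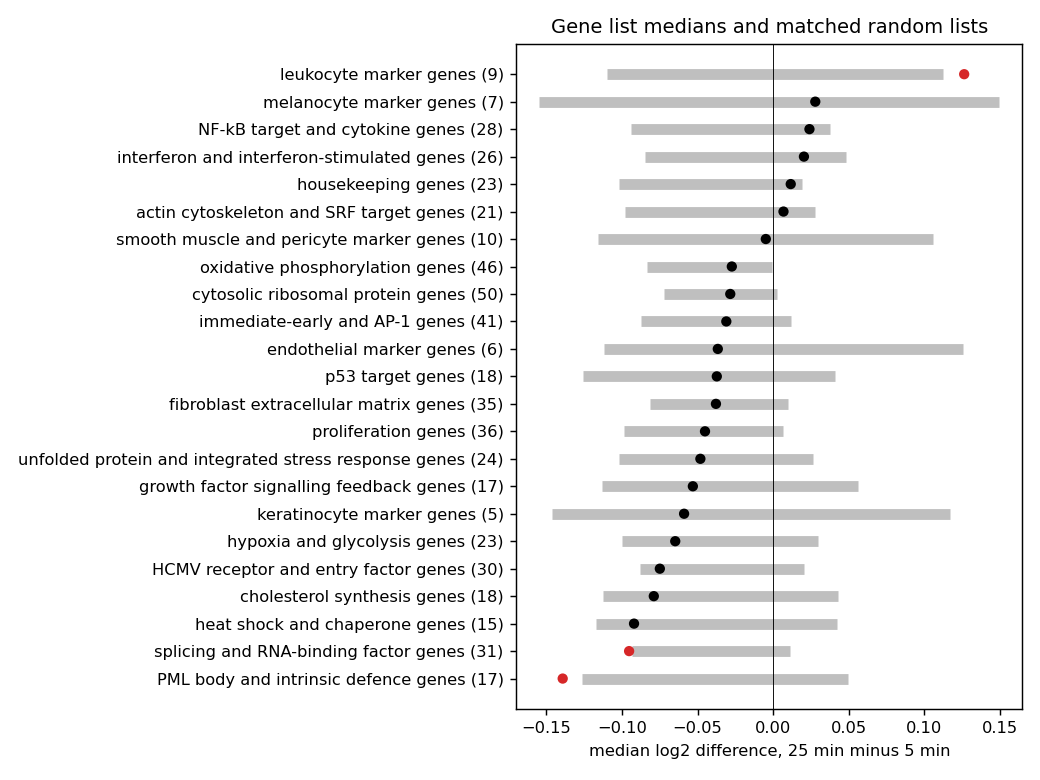
Median log2 difference (25 min minus 5 min) of each of the 23 lists as a point, red where it lies outside the central 95% of 10000 random lists matched on brightness and black otherwise; bars span that range and numbers in brackets count members above the floor on at least 1 array. The leukocyte list, at 0.13, lies above its bar, and the PML body list, at -0.14, and the splicing list, at -0.10, lie below theirs.

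Control probe sets differed between the ends of transcripts. The 5′ probe set of ACTB read 4478 at 5 min and 6011 at 25 min, a log2 difference of 0.42, against 0.13 for its 3′ probe set. For GAPDH the 5′ difference was 0.30 and the 3′ difference -0.01. For the control transcript HUMISGF3A the 5′ difference was 0.72 and the 3′ difference -0.07. For 2 further endogenous controls the 5′ probe sets were below the floor on both arrays, and the 5′ minus 3′ differences were -0.10 and 0.18. The 18 probe sets of spiked hybridisation controls differed by a median of 0.11, from -0.06 to 0.21, and the 9 of them used for scaling by a median of 0.11 as well.

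**Figure D4:**
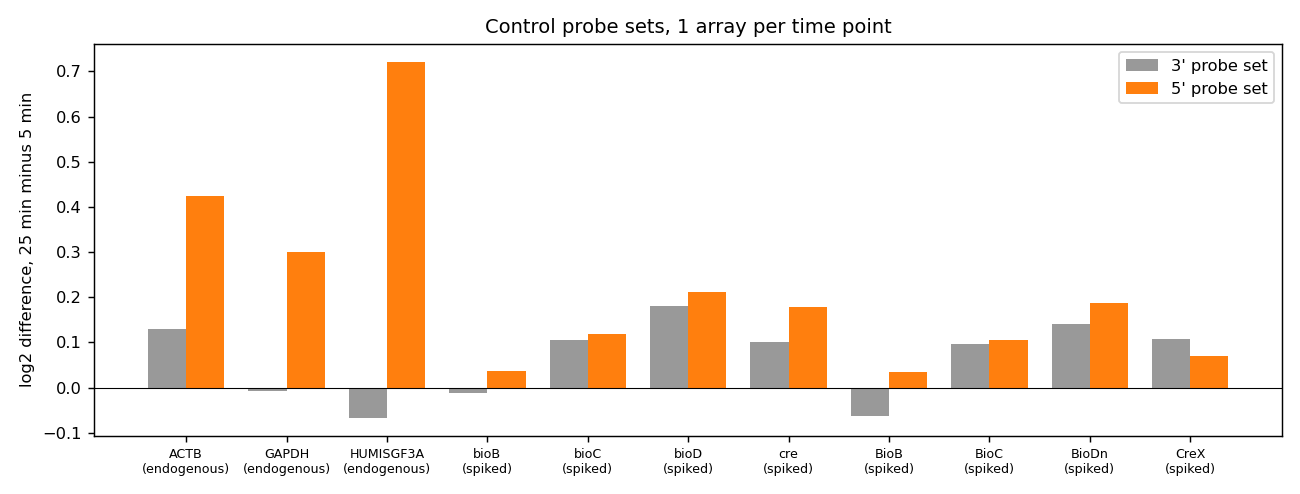
Log2 difference (25 min minus 5 min) of the 3′ (grey) and 5′ (orange) control probe sets of the 3 endogenous transcripts with 5′ probe sets above the floor and of the spiked ones, which have 2 sets of probe sets, with 1 array per time point. The 5′ bars of the endogenous transcripts reach 0.42, 0.30 and 0.72, and those of the spiked hybridisation controls stay at 0.21 or below.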

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

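Scaling to the spiked controls and removal of values below the 1st percentile were chosen after the data were seen. Centring, quantile normalization and loess kept the counts of differing probe sets and genes within 1.5 times, except that loess gave 2 genes lower by 2-fold against 1. The floor and the threshold moved counts most often. With the floor at the 50th percentile, 11 genes were higher and 3 lower, against 7 and 1, and with it at the 75th, 2 were higher and 0 lower, with 12 probe sets higher and 3 lower, against 23 and 6. With no floor, 56 genes were higher and 9 lower, and 147 probe sets higher and 24 lower, which brings in dim signals near background, and no bounds can be given. At 1.5-fold, 19 genes were higher and 12 lower, and 117 probe sets higher and 39 lower, with bounds for 103 probe sets higher and 16 lower, against 62 and 10. At 3-fold, 3 genes were higher, 4 probe sets higher and 3 lower, with bounds for 20 genes higher and 3 lower, against 31 and 5, and 34 probe sets higher. The mean or median of a gene's probe sets, with bounds included, left 0 genes lower. An offset of 32 left 14 probe sets higher, scaling to the spiked controls 15, and removal of probe sets whose names end in x_at or s_at 12 with the floor set anew, and 9 with it kept. That last removal moved the median of MALAT1 to -0.89, on the 1 probe set left to it, and reversed NMRK1 to -0.0511, measured then on another probe set. Without values below the 1st percentile, 6 probe sets had a bound lower. Beyond what these settings do by construction, the cause was not tested. Of list medians, 319 values stayed within 0.15, the typical disagreement between probe sets, and 3 moved. The main medians lay between -0.14 and 0.13, so a median could vanish or change sign and still count as stayed. This tally thus does not show that list medians are stable. Of list percentiles, 301 stayed inside or outside the central 95% as before and 21 did not. Of named genes, 1418 values stayed within 0.15, 152 moved and 1 reversed. Only genes at or beyond 2-fold in the main values could count as reversed. Smaller differences that changed sign count as stayed or moved. VEGFA, for example, was at -0.44 by its brightest probe set and 0.22 by the median of its 4. The PML body list was below the central 95% of random lists in 12 of 14 alternatives, the splicing list in 5, and the melanocyte list in 1. The leukocyte list was above it in 8, and the NF-kB list in 3. Centring and scaling to the spiked controls are among these alternatives but shift every gene alike. They cannot move a list percentile, so they say nothing on how stable it is. No paired analysis was possible because each time point had 1 array, and for the same reason no array could be left out.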

Other observations

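Counts of genes with several differing probe sets, the comparison of dim with bright probe sets, the share of very low 5 min values and both tests on control transcripts were chosen after the values were seen; the other tests below were chosen before. Looking at genes by all their probe sets, 11 of 4173 genes had at least 2 probe sets higher by 1.5-fold at 25 min, against a median of 1 and a highest value of 5 when differences were reassigned to genes at random 10000 times. They were ARHGDIA, CD44, COL6A1, DDX3X, EGFR, FGF5, LOX, SCD, SEPTIN2, THBS1 and TMED2. THBS1 also had a probe set lower by over 1.5-fold, with a range from -0.93 to 1.31 over 6. COL6A1, a chain of collagen VI, had 3 of 5 probe sets higher by 1.5-fold, with a highest difference of 1.58, but -0.07 in its brightest. LOX, which crosslinks collagen, reached 1.02 with 0.07 in its brightest, and TMED2, of vesicle transport, 1.04 with -0.02. FGF5 was the 1 gene of the 11 whose brightest probe set was itself higher by 1.5-fold.

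In the lower direction 2 genes had at least 2 such probe sets, which the highest of the random reassignments equalled. MALAT1 was joined by DDX17, an RNA helicase that acts in splicing and microRNA processing. DDX17 had a median of -0.65 over 4 probe sets, from -0.96 to -0.38, with 3 of them lower by at least 1.5-fold. Over genes with several measured probe sets, the dimmest differed from the brightest by a median of 0.03 where their brightness lay within 1 log2 unit, 0.09 at 1 to 2 units and 0.07 beyond, and by 0.00397, 0.04 and 0.04 after loess. The random reassignment kept to bins of brightness but took no account of overlap between probe sets of a gene or of the end of the transcript that they read.

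The lower signal of MALAT1 at 25 min was weighed against 2 technical explanations. A trend with intensity is argued against, since its brightest probe set stood at -0.867 after subtraction of a loess trend. More unspliced or genomic sequence on the 5 min array was predicted to lower probe sets listed to no gene at 25 min. These lay 0.0294 above single-gene probe sets of like brightness (95% bootstrap interval over probe sets 0.0221 to 0.0363, 2235 probe sets). The annotation does not show that these probe sets read such sequence, so the comparison cannot decide this. A difference in recovery of nuclear RNA and an effect of infection time may each account for it, and neither was tested, since no mock-infected array was analysed here.

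Some of the probe sets above the floor at 25 min alone may reflect failed readings of single probe sets on the 5 min array. Of the 62 that were at least 2-fold higher, 37.1% had a 5 min value below the 5th percentile of that array, against 8.33% of all probe sets below the floor there, and 5 of the 10 at least 2-fold lower had such a low value at 25 min. The rest of the 62 had no such low value. Among them were the named genes with the largest bounds, ARNT, ESPL1, FER1L5, ABCG5 and PKD1. These read 47.5 to 105 at 5 min, above that percentile of 43.9, so failed 5 min readings are not shown for them. A higher level of the genes' transcripts at 25 min was not seen in their other probe sets above the floor on both arrays. The median difference of these was 0.00445 (95% bootstrap interval over probe sets -0.0712 to 0.0819, 35 probe sets of 18 genes). Probe sets that rose from below the floor were left out of this median by its definition. It argues against a rise only for transcripts already read above the floor at 5 min. Of those 35 probe sets, 2 were higher by 1.5-fold. Transcript forms read by a single probe set, and genes with no other measured probe set, stay open.

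The higher 5′ signal of control transcripts at 25 min is consistent with less 5′ sequence in the labelled RNA of the 5 min array. In the 3 endogenous transcripts with 5′ probe sets above the floor the 5′ difference exceeded the 3′ difference by at least 0.296. In the spiked hybridisation controls, which are added after labelling, it did so by at most 0.0977. The 2 endogenous controls with 5′ probe sets below the floor on both arrays, with gaps of -0.105 and 0.184, were left out. So were the Dap, Lys, Phe, Thr and Trpn control probe sets, whose 5′ probe sets were below the floor on both arrays. Their gaps went both ways. The 5′ and 3′ differences were 0.07 and -0.23 for r2-Bs-dap, but 0.14 and 0.21 for PheX. Scaling between the arrays by 1 factor is argued against, since it moves both ends of a transcript alike and the median gap between them was 0.309. Both comparisons use the same 3 transcripts in which the gap was seen, so neither is a separate test of it. Whether the RNA or its labelling differed was not tested, and with 1 array per time point this difference goes along with infection time.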
